A study of Rattus norvegicus with 16 samples.

How the data were processed

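The series holds 16 Affymetrix arrays of isolated corticotropes from pituitary glands of 21-day-old Wistar rats, 4 for each of control, CRH, IL-6 and eNampt. Per the labels' protocols, the glands were dissociated with collagenase and cultured, and corticotropes were taken from the culture on biotin-binding beads with an anti-CRHR1 antibody, whereas the series' design text speaks of an anti-CRH antibody. The cells were kept in DMEM/F12 with 10% fetal bovine serum and 0.05 µg/l FGF, exposed to the ligand for 24 h and extracted with Trizol, and biotinylated target was made from 5 ng of total RNA with a Pico amplification kit. The titles of the ligand samples give 24 h, and those of the control samples give no time. Ligand doses and the preparation of eNampt are not given in the sources used here.

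The values are deposited as 1 table of log2 expression per probe set, which the authors made with RMA per the submitters' processing notes. The version of RMA, the probe set level and the genome build are not given in the sources used here, so gene names but no coordinates are reported. The table holds 36685 probe sets on 16 arrays, with array medians from 1.82 to 2.02 and values from 0.166 to 11.5. Gene symbols came from the array's annotation and were brought to current rat names through Entrez identifiers, which matched 14670 probe sets. A single gene symbol was found for 14824 probe sets, several for 829 and none in the annotation used here for 21032. Probe sets with several symbols or none were left out of the gene comparisons and used only in an alternative. For the 234 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 14557 genes. No filter on dim probe sets was applied.

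Groups were taken from the sample titles. All comparisons used limma 3.58.1 in R 4.3.3: 1 mean per group was fitted to all 16 arrays, with empirical Bayes variances (no trend, not robust), two-sided moderated tests of the 3 ligands against control and of the 3 pairs of ligands, and a moderated F test over the 3 differences from control. Adjusted p are Benjamini-Hochberg values over all genes of a comparison, and a gene was called at an adjusted p under 0.05. The fit had 12 residual degrees of freedom and 2.28 prior degrees of freedom. The median residual SD was 0.409 (log2), which gives an SE of 0.281 for a difference of 2 groups. For single genes and for array means of gene lists, exact permutation tests over all splits of the arrays were used. The comparisons, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined.

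The fit was tested on simulated data with the means and residual spread of the 14557 genes, drawn independently for each gene, so that correlation between the genes of a list was not tested. It recovered 56.7% of 67 genes raised 2-fold in the eNampt group, 73.1% of 67 raised 4-fold and 90.9% of 66 raised 8-fold. It called 5 unchanged genes. It also called the 1 list that was raised and 0 unchanged lists. With so many genes raised at once, the Benjamini-Hochberg limit is more lenient than in the real comparisons, which called at most 2 genes. All groups were also drawn with equal spread. The shares of genes recovered are thus likely too high for the real comparisons.

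Gene lists were tested with camera at its preset inter-gene correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. Members were also counted as called over all genes and adjusted over the list alone. There were 32 lists with 731 listed genes, 501 of them measured, the smallest share of a list being 40.7%. They covered corticotrope identity, CRH and cAMP-responsive genes, the IL-6 and JAK-STAT3 response, NF-kB targets, interferon-stimulated genes, MHC class I with antigen processing, MHC class II, NAD metabolism, receptors of the 3 ligands, glucocorticoid-responsive genes, secretory granules and exocytosis, the cell cycle, apoptosis and p53 targets, the unfolded protein and integrated stress response, cholesterol, glycolysis and hypoxia, oxidative phosphorylation, cytosolic ribosomal proteins, the circadian clock, oxidative stress and extracellular matrix. Marker lists covered melanotropes, somatotropes, lactotropes, thyrotropes, gonadotropes, folliculostellate and stem cells, posterior lobe glia, endothelium, fibroblasts and mural cells, leukocytes and erythroid cells.

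Genes were named by a rule. For each ligand against control it took the 8 genes each way with the largest change among those called without overlap of the groups or, since under 10 passed, the 4 genes each way with the largest moderated t. Predicted loci, small RNA genes and olfactory, vomeronasal and taste receptor genes were left out. For each list the rule allowed up to 4 called members or, where none passed, up to 2 with the largest moderated t, and for pairs of ligands the 2 genes each way. Pomc, Tbx19, Il6r, Tlr4 and Nr4a1 were always named. Crhr1, Nampt, Il6st and Socs3 were to be named too but had no probe set with a single symbol in the annotation used here and were not analysed here. Genes that passed only when adjusted over the list alone, genes called under an alternative, and Il6, Tnf, Cxcl10, Icam1, Vcam1 and Prxl2a were chosen after their values were seen.

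Alternatives changed 1 choice at a time: quantile normalization repeated on the deposited values, centring on array medians, only the 9746 genes above the median of all values (log2 1.946) on at least 4 arrays, every probe set, the mean over the probe sets of a gene, an intensity trend with robust variances, array quality weights, only the arrays of the 2 groups compared, the replicate number as a block, fold changes of at least 1.5 or 2, an estimated inter-gene correlation, controls split between comparisons, and each array left out in turn. Fits without control arrays 3 and 4, fits with a term for replicates 1 and 2 against 3 and 4, and gene lists with each array left out were added after the data were seen. Unchanged groups sharing the 4 control arrays were simulated 100 times. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.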

Results

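Rat pituitary cells labelled as isolated corticotropes were exposed in culture to corticotropin-releasing hormone (CRH), interleukin-6 (IL-6) or extracellular nicotinamide phosphoribosyltransferase (eNampt) for 24 h. There were 4 arrays per treatment and 4 control arrays, whose titles give no culture time. The comparisons address which transcripts each ligand changed and how the response to eNampt differed from those to CRH and IL-6. Pomc, the gene of the ACTH precursor, was among the brighter transcripts of every group, with mean log2 levels of 7.73 ± 0.364 (SD, n = 4) in control, 8.45 ± 0.216 after CRH, 8.18 ± 0.14 after IL-6 and 8.26 ± 0.274 after eNampt. Control arrays 3 and 4 stood apart from the other arrays. Their 90th percentiles were 4.58 and 4.43 (log2), against 5.37 and 5.51 on control arrays 1 and 2 and 5.07 to 5.45 on the 12 ligand arrays. The median log2 difference of all 14557 genes was 0.102 for CRH against control, 0.086 for IL-6 and 0.064 for eNampt. A list of unchanged genes of ordinary level would lie slightly above 0 in each. For bright genes this baseline is too low. Random lists as bright as the oxidative phosphorylation genes had median differences of 0.431, 0.413 and 0.505, so positive means of bright lists against control need not be particular to those lists. Since the labels do not say whether the 4 arrays of a group came from separate cultures or animals, the p-values measure only the spread between these samples, which may be technical.

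After CRH, Pomc was 1.65-fold higher than in control (log2 difference 0.72 ± 0.193 SE, n = 4 per group). All 4 CRH arrays lay above all 4 control arrays. It rose when adjusted over the list alone, with adjusted p = 0.0176 among the 8 measured corticotrope identity genes and 0.0485 among the 22 genes that respond to CRH and cAMP, but not over all genes (adjusted p = 0.479). In an exact two-sided permutation test of Pomc the p was 0.0286, the smallest that 4 against 4 arrays can give, and 0.214 after Benjamini-Hochberg adjustment over 15 such tests. Creld2, an endoplasmic reticulum chaperone gene, rose by 1.51 ± 0.31 and Myl9, a myosin light chain gene of contractile cells, by 1.05 ± 0.243, again only when adjusted over the list alone (adjusted p = 0.00461 and 0.00922) and not over all genes (0.265 and 0.355). Nr4a2, an orphan nuclear receptor gene induced by cAMP, had a log2 difference of 0.71 ± 0.226 (adjusted p = 0.661). Repeating the quantile normalization lowered the differences of Pomc, Myl9 and Nr4a2 to 0.40, 0.64 and 0.30.

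Across all genes, limma called 0 genes between CRH and control at adjusted p under 0.05, the smallest adjusted p being 0.158. At an unadjusted p under 0.05 there were 921 genes, 810 of them higher after CRH and 111 lower, where chance gives 728. The groups did not overlap for 364 genes, or 2.5% where chance gives 2.86%. The nearest to the threshold were Mlx (log2 difference 1.75 ± 0.298 SE), Tspan13 (1.66 ± 0.287), Lin7c (2.33 ± 0.412) and Tex261 (1.85 ± 0.335) on the higher side and Prxl2a-ps1 (-1.22 ± 0.191) and Zfp697 (-1.60 ± 0.291) on the lower side, all with adjusted p = 0.158. They were followed by Tma7l1 (-0.96, adjusted p = 0.357) and Gpd1 (-0.71, 0.430). Leaving out control array 2 gave 2 genes (Txndc12 and Xbp1), leaving out control array 4 gave 1 (Tma7l1), and repeating the quantile normalization gave 2 (Prxl2a-ps1 and Zfp697).

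Oxidative phosphorylation genes were higher after CRH in 32 of 33 measured members, with a mean log2 difference of 0.69 ± 0.425 (SE over array means). Sdhc at 1.03 and Ndufs8 at 1.43 were the members with the largest moderated t. Genes of the unfolded protein and integrated stress response were higher in 18 of 20 members (mean 0.53 ± 0.219), among them Creld2 and Xbp1 (0.92), the transcription factor of that response. Ndufs8 was at 0.91 and Xbp1 at 0.57 without control arrays 3 and 4, and Xbp1 was at 0.47 after repeated quantile normalization. Genes of secretory granules and exocytosis were higher in 18 of 21 members (mean 0.52 ± 0.125), for example the granin gene Scg2 (0.73) and the granule priming factor Cadps (1.43). Cadps was bright on CRH array 3 alone, and its difference was 0.53 without that array. Scg2 was at 0.33 without control arrays 3 and 4. These 3 lists were called by camera, with adjusted p = 1.97e-06, 0.00133 and 0.0339, against adjusted p = 0.646 with an estimated correlation for each. No member passed over all genes. Adjusted over the list alone 0 oxidative phosphorylation genes, 1 stress response gene (Creld2) and 0 secretory genes did. Oxidative phosphorylation and the stress response were lower on control arrays 3 and 4 than on control arrays 1 and 2, while the secretory list was lowest on control arrays 2 and 4. Without control arrays 3 and 4 the means of the 3 lists were 0.16, 0.19 and 0.44 with adjusted p = 0.407, 0.407 and 0.0951. No list was then called, and 2 genes were (Rap2a and Use1). The secretory list also lost its call without control array 2 (adjusted p = 0.226) or 4 (0.130) or CRH array 1 (0.106) or 4 (0.111). Repeated quantile normalization ended it (0.166) as well as that of the stress response (0.0775). The call of the secretory list was also lost among genes above the median of all values (0.0845).

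After IL-6, genes of the IL-6 and JAK-STAT3 response were higher in 19 of 20 measured members with a mean log2 difference of 0.33, which camera did not call (adjusted p = 0.255), and of 0.17 without control arrays 3 and 4. Its members with the largest moderated t were A2m, the acute-phase protease inhibitor alpha-2-macroglobulin (0.88 ± 0.387 SE), and Lcn2, the siderophore-binding lipocalin (0.98 ± 0.487), neither of which passed (adjusted p = 0.860 for both). The difference of Lcn2 was 0.04 without control arrays 3 and 4. Fdft1, the squalene synthase gene, rose by 0.97 ± 0.243 when adjusted over the list alone (adjusted p = 0.0187, against 0.611 over all genes), as 1 of 15 measured genes of cholesterol synthesis and uptake. The immediate early gene Egr1 had a log2 difference of 0.64, Scg2 of 0.76, the chemokine gene Ccl5 of 0.86 and Isl1 of 1.35, all without passing (adjusted p from 0.714 to 0.860). Pomc was 1.37-fold higher (log2 0.45 ± 0.193, exact permutation p = 0.0571, 0.286 over the 15 tests). After repeated quantile normalization Pomc was at 0.24, A2m at 0.53, Egr1 at 0.35, Scg2 at 0.49 and Fdft1 at 0.60. Scg2 was at 0.35 without control arrays 3 and 4. Oxidative phosphorylation was the 1 list called by camera, higher in 33 of 33 members with a mean of 0.60 ± 0.411 (Sdhc 0.78, adjusted p of the list = 4.91e-05). It was lost at adjusted p = 0.592 with an estimated correlation. Of its members 0 passed over all genes and 0 adjusted over the list alone. This list again moved with control arrays 3 and 4. It had a mean of 0.07 without them (adjusted p = 0.609) and of 0.25 without control array 3 alone (0.208). Repeated quantile normalization also ended the call (0.0529). Among replicates 1 and 2 its mean difference was -0.17, among replicates 3 and 4 it was 1.36.

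One gene passed over all genes after IL-6: Prxl2a-ps1, a pseudogene of the peroxiredoxin-like gene Prxl2a, fell by 1.42 on the log2 scale (SE 0.191, means 2.16 ± 0.162 and 3.59 ± 0.159, adjusted p = 0.0412), with all 4 IL-6 arrays below all 4 control arrays. Its probe set may share sequence with Prxl2a, whose own probe set had a log2 difference of 0.16 ± 0.449, so the identity of the transcript is uncertain. Prxl2a-ps1 was also lower than control after CRH (-1.22) and eNampt (-1.24), so its fall was not particular to IL-6. The call was not stable, though the difference stayed between -1.58 and -1.35 in 18 alternatives. The adjusted p was 0.136 with the replicate number as a block and 0.0646 with a term for replicates 1 and 2 against 3 and 4. It was also lost among genes above the median (0.10), with an intensity trend and robust variances (0.0927), with array quality weights (0.0613), with only the 8 arrays of the 2 groups (0.165) and without control arrays 3 and 4 (0.144). The call was lost without any 1 of control arrays 1, 2, 3 and 4 (adjusted p = 0.117, 0.0863, 0.0843 and 0.0728) or IL-6 arrays 2, 3 and 4 (0.118, 0.136 and 0.0934). Without IL-6 array 1 it was 1 of 7 genes called. At an unadjusted p under 0.05 there were 806 genes, 644 higher and 162 lower. For 461 genes (3.17% where chance gives 2.86%) the groups did not overlap. Next in the order of the test were Clk4 (1.74), Trim13 (2.11), Gnat1 (1.59) and Tex261 (1.92), all with adjusted p = 0.118. On the lower side came Zfp933 (-1.97, 0.497), Muc1 (-1.07, 0.601) and Cd209fl1 (-0.57, 0.701). Without control arrays 3 and 4 the 1 gene called was Rap2a.

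After eNampt, the central complement gene C3 rose 10.2-fold (log2 difference 3.35 ± 0.395 SE, means 5.75 ± 1.02 and 2.40 ± 0.067, n = 4 each). Pla2g2a, the gene of a secreted phospholipase A2 of inflammation, rose 7.31-fold (2.87 ± 0.338, 5.24 ± 0.907 and 2.37 ± 0.205). Both had adjusted p = 0.00433 and were the 2 genes called over all genes. On all 4 eNampt arrays each lay above every control array. Their control levels lie little above the array medians, where signal over background is low, so the size of these folds is uncertain. Lcn2 was 8.26-fold higher (8.59 ± 0.147 against 5.54 ± 1.21, adjusted p = 0.0627) and the ribonucleotide reductase subunit gene Rrm2 8.17-fold (3.03 ± 0.509, 0.0627), both just short of the threshold. Without control arrays 3 and 4, on which it was low, Lcn2 had a log2 difference of 2.11 in place of 3.05 (adjusted p = 0.127). It was called in 6 of 18 alternatives, among them repeated quantile normalization (2.73, adjusted p = 0.0246). Also short of the threshold were Rnf114 (1.21 ± 0.197, 0.0627; 0.79 after repeated quantile normalization) and Prxl2a-ps1 (-1.24 ± 0.191, 0.0627). Mrgprg (-0.78), Ddn (-0.85) and Ikzf4 (-0.91) were the next lower genes (adjusted p from 0.206 to 0.227). At an unadjusted p under 0.05 there were 1099 genes, 898 higher and 201 lower. For 602 (4.14% where chance gives 2.86%) the groups did not overlap. The excess of higher genes at an unadjusted p under 0.05, seen after all 3 ligands, was small without control. Between eNampt and CRH 373 were higher and 345 lower, and between eNampt and IL-6 254 and 236. It may thus go with the control arrays, 2 of which had low upper quantiles, and need not be an effect of the ligands.

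**Figure D1:**
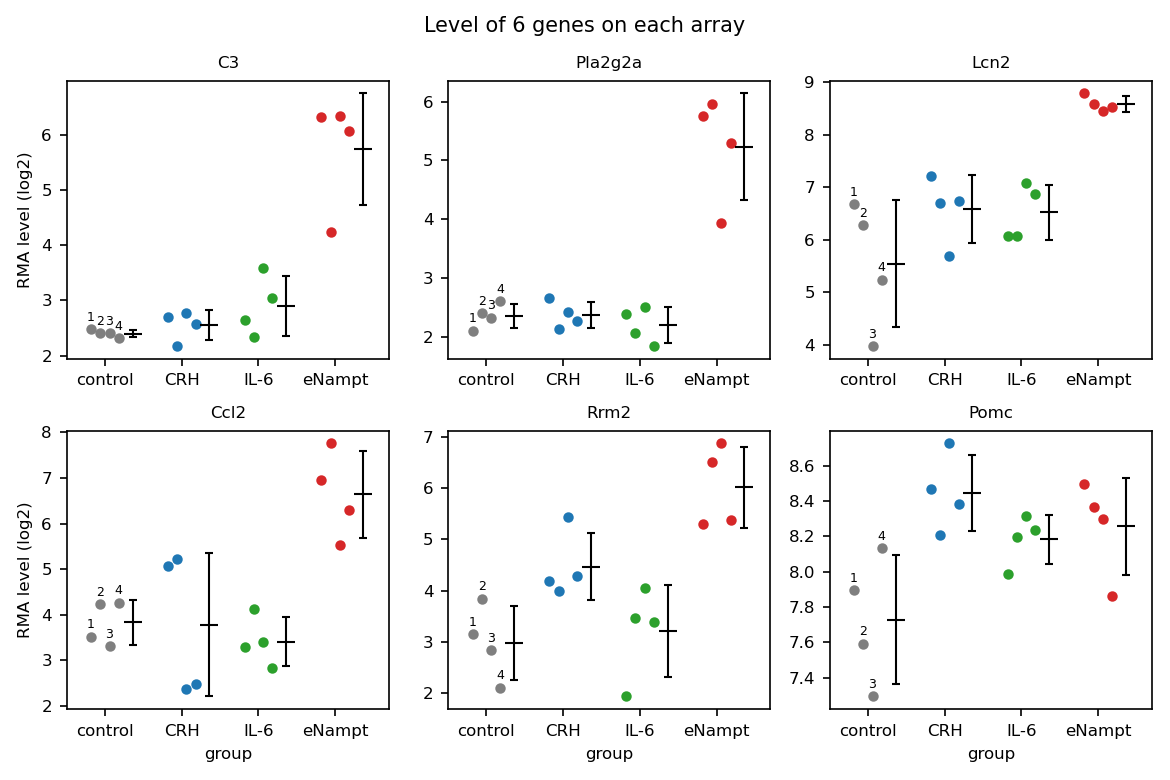
RMA log2 level of C3, Pla2g2a, Lcn2, Ccl2, Rrm2 and Pomc on each of the 16 arrays, grouped as control, CRH, IL-6 and eNampt, with the group mean and SD in black and the control arrays numbered. C3 and Pla2g2a lie between 3.94 and 6.35 on the eNampt arrays and at most at 3.59 on the other 12.

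Targets of NF-kB were higher after eNampt in 32 of 41 measured members, with a mean log2 difference of 0.88 ± 0.272 (SE over array means). Of these, 17 rose when adjusted over the list alone, where 1 (C3) passed over all genes. These members, named after their values were seen, included the monocyte chemoattractants Ccl2 (2.81 ± 0.647 SE) and Ccl7 (2.56 ± 0.751), Ccl20 (1.90), Cxcl1 (1.73), the mitochondrial superoxide dismutase gene Sod2 (1.69), the growth factor genes Csf1 (1.67) and Csf2 (1.39), Bcl2a1 (1.37), Nfkbia, which encodes an inhibitor of NF-kB (1.22), Mmp9 (1.20), Cx3cl1 (1.05), Cxcl6 (1.02), Tnip1 (0.92), Ccl5 (0.76), Il1b (0.74), Lcn2 and C3. Il6 had a log2 difference of 2.04 ± 0.812 without passing (adjusted p = 0.615). Tnf (-0.09), Cxcl10 (-0.11), Vcam1 (0.20) and Icam1 (0.20) differed by about their SE or less, the sign of the difference depending on the alternative for Tnf, Cxcl10 and Icam1. Mean levels of Tnf (1.90 after eNampt, 1.99 in control), Cxcl10 (1.82, 1.92) and Vcam1 (1.85, 1.66) lay near or below the array medians. Their differences carry little signal and do not tell whether these genes responded. Icam1 was brighter (4.65, 4.45). The list was called by camera (adjusted p = 4.03e-10), also with each of the 8 arrays left out (0.71 to 1.10), but not at adjusted p = 0.144 with an estimated correlation. It was low on control arrays 3 and 4 (array means 2.56 and 2.81) and high on control array 2 (3.75). Without control array 2 the differences of Ccl7 and Cxcl1 were 3.52 and 2.35. Those of Ccl7, Ccl20, Csf1, Cxcl1, Csf2, Il6, Mmp9 and Nfkbia were 1.57, 1.21, 0.98, 0.81, 0.75, 0.70, 0.61 and 0.57 without control arrays 3 and 4. That of Il6 was 1.34 without control array 3, that of Bcl2a1 0.87 without eNampt array 2 and that of Tnip1 0.50 after repeated quantile normalization. Without arrays 3 and 4 the list's mean was 0.49 (adjusted p = 9.81e-07).

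Genes of the cell cycle were higher after eNampt in 24 of 25 measured members (mean 1.03 ± 0.319). Of these, 6 rose when adjusted over the list alone, where 0 passed over all genes. They were Rrm2, the replicative helicase genes Mcm6 (1.48 ± 0.331) and Mcm2 (1.36 ± 0.349), and the mitotic genes Kif20a (1.95 ± 0.471), Plk1 (1.56 ± 0.384) and Tpx2 (1.47 ± 0.359). Camera called the list with adjusted p = 4.03e-10, and adjusted p = 0.144 with an estimated correlation. Control arrays 3 and 4 lay low here too (3.47 and 3.60 against 4.20 and 4.84), and without them the mean was 0.54 (3.24e-05) and the difference of Tpx2 was 0.88.

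The IL-6 and JAK-STAT3 list was higher after eNampt in 17 of 20 members (mean 0.51 ± 0.0961, camera adjusted p = 0.00702, adjusted p = 0.144 with an estimated correlation). Lcn2 rose when adjusted over the list alone (0.000384), and Timp1, an inhibitor of metalloproteinases, was at 0.60. Genes that respond to CRH and cAMP were higher in 17 of 22 members (mean 0.46 ± 0.146, adjusted p = 0.00386, adjusted p = 0.150 with an estimated correlation). The immediate early gene Fos rose by 0.90 ± 0.218 when adjusted over the list alone (0.0212), and Nr4a2 was at 0.71. Without control arrays 3 and 4 the means of these 2 lists fell to 0.36 and 0.24 (adjusted p = 0.0254 for both). Both were lost after repeated quantile normalization (means 0.35 and 0.24, adjusted p = 0.0675 and 0.312), where Timp1 was at 0.20, Fos at 0.59 and Nr4a2 at 0.28. Among genes above the median both calls were also lost (0.105 for both), though the means did not fall (0.58 and 0.46). The CRH and cAMP list was higher in 18 of 22 members after CRH and in 17 of 22 after IL-6. Camera called neither (means 0.31 and 0.28, adjusted p = 0.102 and 0.183). Without control arrays 3 and 4 these means were 0.09 and 0.07. On this list the eNampt arrays lay 0.16 above the CRH and IL-6 arrays (SE 0.0881). The exact permutation p was 0.0869, or 0.397 adjusted over all lists. The list's rise was thus not shown to be particular to eNampt. After eNampt, genes of cholesterol synthesis and uptake were higher in 13 of 15 members (mean 0.58 ± 0.249). Fdft1 (1.09 ± 0.243) and Pmvk, the phosphomevalonate kinase gene (1.15 ± 0.352), rose when adjusted over the list alone (0.00741 and 0.0402). The oxidative stress list was higher in 17 of 19 members (mean 0.45 ± 0.261), with Sod2 passing over the list alone (0.00158). The stress response list of the endoplasmic reticulum was higher in 18 of 20 (0.43 ± 0.207, Creld2 1.00 as an example) and oxidative phosphorylation in 33 of 33 (0.67 ± 0.41, Sdhc 0.72), with 0 members adjusted over the list alone in the last 2. None of the members of these 6 lists passed over all genes. Camera called these 4 at adjusted p = 0.00402, 0.00402, 0.00568 and 7.19e-07, against adjusted p = 0.225, 0.435, 0.371 and 0.450 with an estimated correlation. All 4 moved with control arrays 3 and 4 and were not called without them (means 0.23, 0.03, 0.09 and 0.15; adjusted p from 0.116 to 0.778). Without control array 3 alone the oxidative stress list was at 0.31 (0.0509). Repeated quantile normalization lowered Fdft1 to 0.64 and Creld2 to 0.66 and ended the first 3 calls (means 0.34, 0.24 and 0.19, adjusted p = 0.184, 0.191 and 0.507). The limit to genes above the median also ended them (0.0852, 0.121 and 0.121), though the means did not fall (0.58, 0.46 and 0.43).

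**Figure D2:**
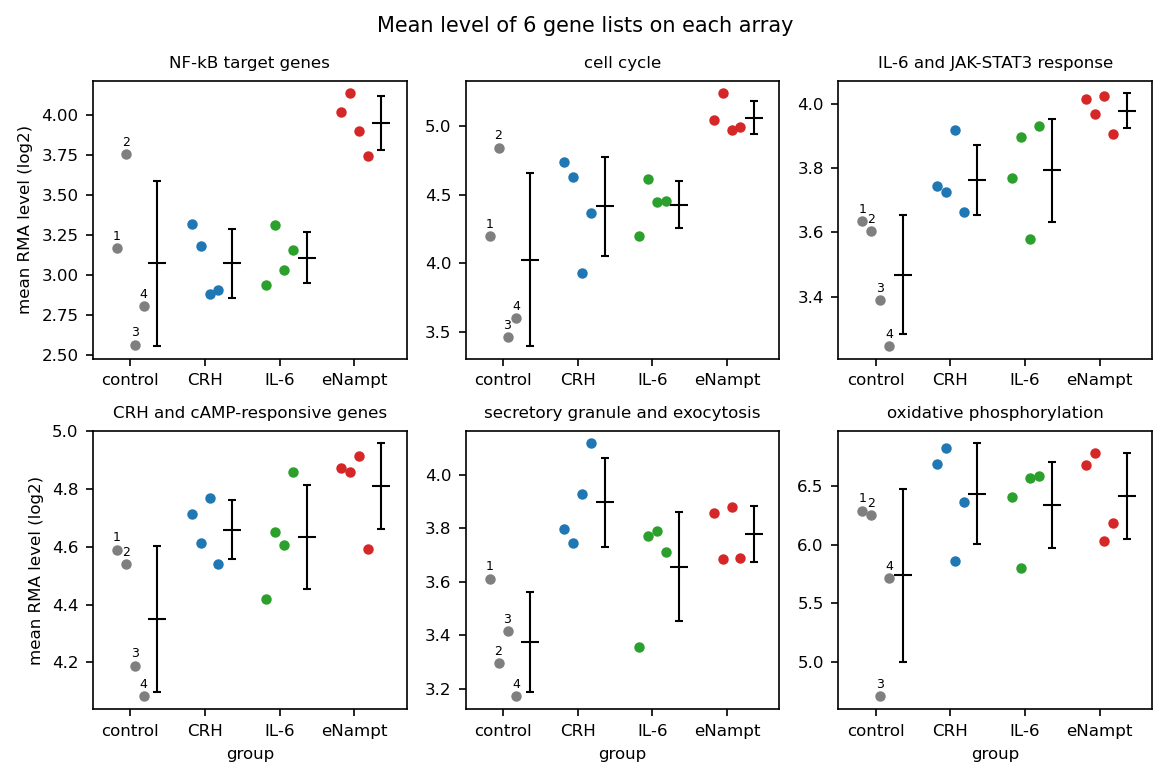
Mean RMA log2 level over the measured members of 6 gene lists on each of the 16 arrays, with the group mean and SD in black and the control arrays numbered. On the NF-kB target list the eNampt arrays lie between 3.74 and 4.14 and the CRH and IL-6 arrays between 2.88 and 3.32. Control arrays 3 and 4 lie lowest on the cell cycle and oxidative phosphorylation lists.

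The calls of C3 and Pla2g2a against control were kept with each of the 8 arrays left out. The count of genes moved from 2 to 14 without control array 2, to 6 without control array 1, to 4 without control array 4, eNampt array 2 or eNampt array 3, and to 5 without eNampt array 4. Without control array 2 the genes called included Lcn2, Ccl7, Sod2, Rrm2, Plk1 and Tpx2. Both calls ended when only the 8 arrays of the 2 groups were fitted (adjusted p = 0.162 for each, 0 genes called) and without control arrays 3 and 4 (C3 3.31, adjusted p = 0.0777, and Pla2g2a 2.98, 0.0519, with 0 genes called). In these fits fewer arrays estimate the spread, and the groups differed in spread. The SD of C3 was 1.015 after eNampt against 0.067 in control, 0.269 after CRH and 0.545 after IL-6. That of Pla2g2a was 0.907 against 0.205, 0.225 and 0.305. The main fit shares the spread of a gene over all groups, so it understates that of the eNampt arrays for both genes.

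Against CRH and against IL-6, eNampt raised the same 2 genes. C3 was 9.17-fold above its level after CRH (log2 3.20 ± 0.395 SE, adjusted p = 0.00758) and 7.20-fold above that after IL-6 (2.85 ± 0.395, 0.0290). Pla2g2a was higher 7.27-fold (2.86 ± 0.338, 0.00758) and 8.15-fold (3.03 ± 0.338, 0.00449), with no overlap between the arrays in any of these. NF-kB targets were higher than after CRH in 33 of 41 members (mean 0.88 ± 0.137) and than after IL-6 in 33 of 41 (0.84 ± 0.117). Of them 15 and 8 rose when adjusted over the list alone, with C3 the 1 member called over all genes in each. Among these, named after their values were seen, Ccl2 differed by 2.86 ± 0.647 from CRH and 3.23 ± 0.647 from IL-6, Csf2 by 1.62 ± 0.31 and 2.00 ± 0.31, and Lcn2 by 2.00 ± 0.487 and 2.07 ± 0.487. Against CRH alone the 15 also held Nfkbia (1.33), Birc3 (1.96), Il6 (2.22) and Il1a (1.81), and against IL-6 the 8 held Sod2 (1.25) and Cxcl6 (1.21). Il6 was at 1.58 without CRH array 4 and Il1a at 1.21 without eNampt array 2. Camera called the list in both (adjusted p = 6.85e-17 and 3.78e-19). The call against IL-6 held with adjusted p = 0.0463 with an estimated correlation and that against CRH did not, with adjusted p = 0.0728 with an estimated correlation.

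Cell cycle genes were higher after eNampt than after CRH in 22 of 25 members (mean 0.65 ± 0.189) and than after IL-6 in 22 of 25 (0.63 ± 0.105). In each, 1 member rose when adjusted over the list alone (Mcm6, 1.45 ± 0.331, and Rrm2, 2.81 ± 0.509) and 0 over all genes. Camera called both (adjusted p = 4.00e-09 and 2.34e-08, against adjusted p = 0.238 and 0.300 with an estimated correlation). In a test of array means added after the data were seen, the 4 eNampt arrays lay above the 8 CRH and IL-6 arrays by 0.859 (SE 0.105) for NF-kB targets and by 0.638 (SE 0.11) for the cell cycle. Each had an exact two-sided permutation p of 0.00202, the smallest that 495 splits can give, and 0.0323 after adjustment over 32 lists. In the same kind of exact permutation test with 4 against 4 arrays, the 18 list comparisons called by camera had p from 0.0286 to 0.200, at best 0.0571 after Benjamini-Hochberg adjustment over the 18. Against CRH, genes of apoptosis and p53 were lower in 10 of 11 members (mean -0.51 ± 0.122, for example Bax -0.95 and Sesn2 -1.21; adjusted p = 0.0373, and adjusted p = 0.436 with an estimated correlation). Both were brightest on CRH array 2, and without it Bax was at -0.56 and Sesn2 at -0.74. Genes of glycolysis and hypoxia were higher in 11 of 14 (0.34 ± 0.154, for example Pgk1 0.46 and Pfkfb3 0.90; adjusted p = 0.0123, and adjusted p = 0.305 with an estimated correlation). In both lists 0 members passed over all genes or adjusted over the list alone. The first was lost without CRH array 1 or 2 or eNampt array 1, 2 or 3 (adjusted p from 0.0602 to 0.233). The second was lost without CRH array 2 (0.0881) or eNampt array 4 (0.0950), after repeated quantile normalization (0.0968) and among genes above the median (0.0971).

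Lower after eNampt than after CRH, without passing, were the chemokine receptor gene Ackr4 (-2.15 ± 0.391, adjusted p = 0.265) and Mlx (-1.33, 0.673), and lower than after IL-6 were Trim13 (-2.03, 0.128) and Gnat1 (-1.36, 0.274). At an unadjusted p under 0.05 there were 718 genes against CRH and 490 against IL-6, where chance gives 728. The groups did not overlap for 431 (2.96%) and 410 (2.82%). Without CRH array 2 neither C3 nor Pla2g2a passed against CRH (adjusted p = 0.0527 for both, 0 genes), and without eNampt array 4 there were 5 genes. Against IL-6, C3 was lost without IL-6 array 1, 2 or 4 or eNampt array 1, 3 or 4 (adjusted p from 0.0753 to 0.163) and without control arrays 3 and 4 (0.0892), with 1 gene called (Pla2g2a) without IL-6 array 2, IL-6 array 4 or eNampt array 1. In the fit without control arrays 3 and 4, Csf2 was called against CRH (1.62, adjusted p = 0.00373) and against IL-6 (2.00, 0.000356). When only the 8 arrays of a pair of groups were fitted, C3 and Pla2g2a lost their calls (adjusted p = 0.253 for both against CRH; 0.472 and 0.266 against IL-6) and 1 gene, Csf2, was called in each.

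Between CRH and IL-6 limma called 0 genes (smallest adjusted p 0.0742; 578 genes at an unadjusted p under 0.05, where chance gives 728), and camera 0 lists. Gtf2h3 (-1.47 ± 0.211) and Csrnp1 (-0.95 ± 0.142) were lower after CRH with adjusted p = 0.0742, and Mrm2 (1.21) and C2cd2 (1.95) higher with 0.569. The groups did not overlap for 337 genes (2.32% where chance gives 2.86%), and Gtf2h3 without IL-6 array 1, or Gnat1 without IL-6 array 3, was the 1 gene called. Over all 4 groups the moderated F test called 3 genes, C3, Pla2g2a and Prxl2a-ps1 (748 at an unadjusted p under 0.05), which became 7 without control array 2, 1 without eNampt array 3 and 0 without eNampt array 1.

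Nr4a1, an immediate early gene that acts on the Pomc promoter, had a log2 difference of 1.57 ± 0.681 after eNampt (exact permutation p = 0.0286, 0.214 over the 15 tests; adjusted p = 0.638), 0.79 after CRH and 0.83 after IL-6. Without CRH array 4, on which it was low, its difference after CRH was 1.58, and without IL-6 array 1 that after IL-6 was 1.32. The difference after CRH was 0.35 without CRH array 2 and 0.46 without CRH array 3, and repeated quantile normalization gave 0.44 after CRH and 0.50 after IL-6. Pomc after eNampt was at 0.53 ± 0.193 (exact permutation p = 0.0857, 0.321 over the 15 tests) and at 0.24 after repeated quantile normalization. Tlr4 was at 0.62 ± 0.307 after CRH (exact permutation p = 0.143, 0.429 over the 15 tests), 0.04 after IL-6 and -0.12 after eNampt. Its mean levels in control and after IL-6 and eNampt (1.75, 1.79 and 1.63) lay below the array medians, so these differences carry little signal. The value after CRH rests on CRH array 2, without which Tlr4 was at 0.20. Levels of Tbx19, the corticotrope transcription factor, lay below the array medians of 1.82 to 2.02 in all groups (1.59 in control, 1.53, 1.61 and 1.44 after CRH, IL-6 and eNampt), and Il6r, a subunit of the IL-6 receptor, at 2.79, 2.57, 2.87 and 2.77, with log2 differences from control between -0.22 and 0.08.

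The log2 differences from control correlated across genes, which are not independent replicates, with r = 0.574 for CRH and IL-6, 0.572 for CRH and eNampt and 0.663 for IL-6 and eNampt. Unchanged groups that share the same control arrays gave r = 0.498 in 100 simulations, and splitting the controls between the 2 comparisons lowered r to 0.0419, 0.0845 and 0.132. The covariances were 0.0961, 0.109 and 0.121 against 0.0783 in the simulations, which leaves 0.0179, 0.0304 and 0.0425. The simulations gave all groups the same spread, but the control arrays varied more. The SD of their 90th percentiles was 0.545, against 0.138 after CRH, 0.157 after IL-6 and 0.109 after eNampt. The remainder can therefore come from the shared control arrays. No gene was called after more than 1 ligand against control, where independent lists would share 0 for both pairs with CRH and 0.000137 genes for IL-6 and eNampt. With 0, 1 and 2 genes called after CRH, IL-6 and eNampt, this does not tell whether the responses were distinct. Prxl2a-ps1, called after IL-6, was lower than control without overlap after all 3 ligands.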

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

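All tests of other splits of the arrays and the tests of control arrays 3 and 4 on NF-kB targets and on the cell cycle were chosen after the result was seen; the other tests were written down before. The condition on how many leukocyte markers must lie above the median of all values was added after the leukocyte value was seen, and without it that value would count against leukocytes. The comparison with equally bright genes on each array was also added after the percentile was seen.

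Oxidative phosphorylation genes were higher than in control after all 3 ligands (mean log2 differences of 0.69, 0.60 and 0.67). Without control arrays 3 and 4, whose upper quantiles are low, at most a share of 0.236 of these differences was left, so the pattern goes with those 2 arrays. The height of expression stays open: the lowest of the 3 means stood at percentile 98.91 among 10000 random lists matched on mean expression, but such lists lack the correlation between the list's genes (0.491), their medians came to shares of 0.624, 0.693 and 0.75 of the list's means, and the excess over equally bright genes was within its spread between arrays (0.26 ± 0.232 SE, 0.184 ± 0.237 and 0.169 ± 0.232). With the real split counted, as small a camera p came from 6 of 35 splits for CRH (real 6.14e-08, lowest other 7.08e-12), 9 of 35 for IL-6 (1.53e-06, 6.90e-13) and 5 of 35 for eNampt (6.74e-08, 5.66e-11), so chance is not excluded. A lower RNA yield or quality of these 2 control samples is a candidate explanation that the tables do not test.

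NF-kB targets were higher after eNampt. Control arrays 3 and 4 cannot account for all of this, since the 4 eNampt arrays also lay above the 8 CRH and IL-6 arrays (difference 0.859, SE 0.105, exact permutation p = 0.00202). The mean difference from control was 0.88 with all arrays and 0.49 without control arrays 3 and 4, so part of it goes with them. Which cells of the cultures carried the higher levels was not measured here. Leukocytes in the eNampt cultures stay open: their markers differed by -0.00531 (SE 0.0976) from the CRH and IL-6 arrays, but only 8 of 18 lie above the median of all values on 4 arrays, the brightest being Cd14 (4.58 after eNampt, 3.93 after CRH, 3.41 after IL-6) and Fcer1g (3.53, 3.28 and 3.93), and the anti-CRHR1 bead selection of the protocol, which would leave such cells out, was not measured here. Endotoxin carried by the eNampt preparation cannot be told apart from eNampt itself, since no array holds the carrier alone; interferon-stimulated genes, which endotoxin can raise, differed by 0.0012 (SE 0.045). Against control, only the real split gave as small a camera p (1 of 35, 2.52e-11, lowest other 7.86e-10), but the exact permutation p of the array means was 0.0571, so chance is not excluded there. The real split was also alone against CRH (1 of 35, 2.14e-18, lowest other 2.26e-10) and IL-6 (1 of 35, 1.18e-20, lowest other 1.80e-12). These 2 splits argue against chance only without adjustment for the number of lists. With an estimated correlation the camera call was lost against control (adjusted p = 0.144) and CRH (0.0728) and kept against IL-6 (0.0463).

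Cell cycle genes were higher after eNampt, and here too the 4 eNampt arrays lay above the 8 CRH and IL-6 arrays (difference 0.638, SE 0.11, exact permutation p = 0.00202), which control arrays 3 and 4 cannot produce. The mean difference from control was 1.03 with all arrays and 0.54 without control arrays 3 and 4, so part of it goes with them. More dividing fibroblasts in the eNampt cultures cannot be told apart from more dividing corticotropes, since fibroblast and mural markers differed by 0.184 (SE 0.165), with Tagln at 10.12 after eNampt and 10.31 and 10.30 after CRH and IL-6 but Dcn at 5.72 against 4.67 and 4.51. The anti-CRHR1 bead selection of the protocol was to leave fibroblasts out. The share of such cells was not measured here. Tagln, a transcript of fibroblast and mural cells, was bright after each ligand, so the samples may hold them. Dividing cells of other kinds cannot be told apart either. Lactotrope markers differed by 0.108 (SE 0.194) and folliculostellate and stem cell markers by -0.243 (SE 0.19), and such levels do not show which cells divided. Only the real split gave as small a camera p against control (1 of 35 splits, camera p 1.46e-11, lowest other 1.49e-10), CRH (1 of 35, 2.50e-10, lowest other 1.73e-08) and IL-6 (1 of 35, 1.46e-09, lowest other 1.58e-06). This argues against chance only without adjustment for the number of lists. The exact permutation p of the array means were 0.0571 after adjustment over 18 list comparisons. With an estimated correlation all these camera calls were lost (adjusted p = 0.144, 0.238 and 0.300).

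Among the other lists, only the real split gave as small a camera p after eNampt against control for CRH and cAMP-responsive genes (1 of 35 splits, camera p 0.000482, lowest other 0.00271). The same holds for the IL-6 and JAK-STAT3 list (1 of 35, 0.00176, lowest other 0.00392). This argues against chance for each of these 2 lists only without adjustment for the number of lists. The exact permutation p of their array means were 0.0571 after adjustment over 18 list comparisons, and their calls ended with an estimated correlation (0.150 and 0.144). Chance is not excluded for the endoplasmic reticulum stress list (4 of 35, 0.00124, lowest other 0.000342), cholesterol (3 of 35, 0.000736, lowest other 0.000296) and oxidative stress (7 of 35, 0.000754, lowest other 4.81e-05). After CRH it is not excluded for secretory granules (2 of 35, 0.00318, lowest other 0.00259) and the stress list (2 of 35, 8.28e-05, lowest other 5.67e-06). Between eNampt and CRH it is not excluded for apoptosis and p53 (4 of 35, 0.00466, lowest other 0.000224) and glycolysis and hypoxia (2 of 35, 0.00116, lowest other 0.000284).

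For the counts of genes, only the real split gave as many for eNampt against control (1 of 35 splits, real 2, highest other 1), by a margin of 1 gene. A share of 1 in 35 is the smallest this test can give. It was not adjusted over the 7 counts and assumes that the arrays can be exchanged, so it does not exclude chance. The count was 0 with only the arrays of the 2 groups and without control arrays 3 and 4. The same limits on the number of counts and on the margin hold for the F test over 4 groups (1 of 100 splits drawn, real 3, highest other 2). Chance is not excluded for eNampt against CRH (2 of 35, real 2, highest other 3), eNampt against IL-6 (2 of 35, real 2, highest other 2) and IL-6 against control (3 of 35, real 1, highest other 9). Neither is it for CRH against control (35 of 35, real 0, highest other 104) and CRH against IL-6 (35 of 35, real 0, highest other 2). The split with 104 genes set control arrays 1 and 2 with CRH arrays 1 and 2 against control arrays 3 and 4 with CRH arrays 3 and 4. This points to a structure of these samples other than the treatment. With a term for replicates 1 and 2 against 3 and 4 in all groups, that term called 0 genes (1408 at an unadjusted p under 0.05 with limma, where chance gives 728). No comparison of 2 groups reached 1408, the most being 1099 for eNampt against control, though the term sets more arrays on each side. The difference of replicates 1 and 2 from 3 and 4 ran the same way across genes in control (r = 0.153), CRH (0.206) and eNampt (0.273) as in the other groups together but not in IL-6 (-0.128). The labels give no batch for it.

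In 27 of 384 groups of 4 arrays tested, 1 array lay far from the other 3, where chance gives about 1 in 20 groups. The values below are its gap to the nearest array over the range of the group. For the 90th percentile of the array it was CRH array 3 (0.844; 5.10 against 5.36 or more). Mean levels of lists gave CRH array 4 for the unfolded protein and integrated stress response (0.83, low) and eNampt array 4 for CRH and cAMP-responsive genes (0.831, low). Control array 2 was high for Xbp1 (0.917), Ccl7 (0.964; 5.84 against 2.12), Plk1 (0.93) and Birc3 (0.953; 5.18 against 2.78). Control array 1 was high for Tnf (0.898; 2.26 against 1.91). Control array 4 was low for Tma7l1 (0.877) and Timp1 (0.875). CRH array 3 was high for Cadps (0.847; 6.58 against 3.23) and low for Ndufs8 (0.847), Ccl20 (0.858) and Mmp9 (0.843). CRH array 4 was high for Tbx19 (0.86) and low for Trim13 (0.892), and CRH array 1 was high for Cd209fl1 (0.852). IL-6 array 1 was low for Lin7c (0.862) and Nr4a1 (0.852). IL-6 array 2 was high for Kif20a (0.895) and low for Mcm6 (0.932), and IL-6 array 4 low for Il6 (0.897). eNampt array 2 was low for C3 (0.876; 4.24 against 6.08 or more) and Mmp9 (0.877) and high for Ikzf4 (0.93). eNampt array 3 was high for Rnf114 (0.832) and eNampt array 1 high for Ddn (0.849).

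Among probe sets without a gene symbol in the annotation used here, which no comparison above uses, limma called 1 in eNampt against control when every probe set was tested (probe set 17804466, log2 difference 1.65 ± 0.216 SE, adjusted p = 0.0276). It called 2 in eNampt against IL-6 (17601203 and 17601537, both -1.46 ± 0.203, adjusted p = 0.0423).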

How the results depend on the processing

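The fits without control arrays 3 and 4, those with a term for replicates 1 and 2 against 3 and 4, and the lists with 1 array left out were chosen after the data were seen. No result changed direction past its threshold under any alternative run. For counts and correlations 48 values moved and 110 stayed within their limits. For list means 54 lost the call with the same direction and 192 kept it. For single genes 31 lost a call, 36 gained one and 2208 kept their side of the threshold. Counts that moved are given by setting, and the cause was not tested. Repeated quantile normalization gave 2 genes for CRH against control and 4 for eNampt against control. IL-6 against control fell to 0 and eNampt against IL-6 rose to 4 among genes above the median, to 0 and 4 with every probe set, to 0 and 5 with an intensity trend and robust variances, and to 0 and 6 with array quality weights. With only the arrays of the 2 groups, IL-6 against control gave 0, eNampt against control 0, eNampt against CRH 1 and eNampt against IL-6 1. Without control arrays 3 and 4, CRH against control gave 2 and eNampt against control 0. With a term for replicates 1 and 2 against 3 and 4, IL-6 against control gave 0 and eNampt against IL-6 gave 4 (C3, Pla2g2a, Ccl2 and Csf2). With the controls split, the correlations fell to 0.0419 (CRH and IL-6), 0.0845 (CRH and eNampt) and 0.132 (IL-6 and eNampt), which goes with the shared control arrays. Leaving out 1 array gave 0 to 2 genes for CRH against control, 0 to 7 for IL-6, 2 to 14 for eNampt, 0 to 5 for eNampt against CRH, 1 to 3 for eNampt against IL-6, 0 to 1 for CRH against IL-6 and 0 to 7 for the F test.

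With the replicate number as a replicate block, IL-6 against control gave 0 genes and eNampt against control 4 (C3, Lin7c, Pla2g2a and Rrm2), and no other count moved by over 1.5 times. The labels do not say that the numbers pair the arrays, and the values do not settle it. The deviations of the 24 pairs of the same number correlated with r from -0.184 to 0.305 (mean 0.0543), 8 of them over 0.1. The 72 pairs of other numbers had r from -0.245 to 0.278 (mean -0.0183), so the ranges overlap. With these numbers of pairs, the 8 of 16 arrays that correlated best with an array of their own number are more than chance would give. Both values lean toward a shared effect of the number, which the main fit does not model. Signal limits the rest: 9746 of 14557 genes lay above the median of all values on 4 arrays, and levels near it carry little signal over background.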

Other observations

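Some transcripts of other pituitary cells were bright in all groups. Prl, the prolactin gene of lactotropes, had mean log2 levels of 10.78 in control and 10.95, 10.64 and 10.76 after CRH, IL-6 and eNampt. Cga, the common hormone subunit, lay at 7.21, 7.83, 7.98 and 7.90, and Gh1 5.12, 5.57, 5.65 and 5.82. Fibroblast and mural transcripts were bright too, Tagln at 10.24, 10.31, 10.30 and 10.12 and Col1a1 at 6.59, 7.02, 6.81 and 6.94. The leukocyte gene Ptprc lay at 1.57, 1.43, 1.47 and 1.46, below the array medians. These genes were picked from the marker lists after their levels were seen. The lists as a whole had lower mean levels, from control to the highest ligand group 4.87 to 5.60 for lactotropes, 4.83 to 5.23 for fibroblasts and mural cells, 3.34 to 3.56 for gonadotropes, 2.99 to 3.44 for thyrotropes, 2.84 to 3.40 for melanotropes and 2.71 to 2.91 for somatotropes.

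Camera called 11 of the 32 lists in at least 1 comparison and 21 in none (adjusted p from 0.123 to 0.996). The mean log2 differences of the latter against control are given for CRH, IL-6 and eNampt in turn. They were 0.33, 0.34 and 0.21 for corticotrope identity, 0.14, 0.16 and 0.15 for interferon-stimulated genes, 0.20, 0.18 and 0.33 for MHC class I and antigen processing, 0.27, 0.04 and 0.24 for MHC class II. They were 0.18, 0.13 and 0.18 for NAD metabolism, 0.01, -0.04 and 0.15 for receptors of the 3 ligands, 0.22, 0.15 and 0.27 for glucocorticoid-responsive genes, 0.22, 0.14 and 0.27 for ribosomal proteins, 0.22, 0.24 and 0.24 for the circadian clock and 0.17, 0.25 and 0.26 for extracellular matrix. Among markers they were 0.16, 0.35 and 0.55 for melanotropes, 0.20, 0.02 and 0.02 for somatotropes, 0.26, 0.72 and 0.60 for lactotropes, 0.45, 0.45 and 0.17 for thyrotropes. They were 0.20, 0.23 and 0.10 for gonadotropes, 0.54, 0.57 and 0.31 for folliculostellate and stem cells, 0.07, 0.02 and 0.18 for posterior lobe glia, 0.10, 0.06 and 0.01 for endothelium, 0.19, 0.23 and 0.40 for fibroblasts and mural cells, -0.03, -0.04 and -0.04 for leukocytes and -0.01, -0.02 and -0.06 for erythroid cells. Of these 63 differences, 22 had another sign without control arrays 3 and 4, so the directions are not settled. Those of ribosomal proteins were then -0.16, -0.24 and -0.11, of glucocorticoid-responsive genes -0.11, -0.19 and -0.07, of NAD metabolism -0.06, -0.11 and -0.06, of MHC class I -0.13, -0.15 and 0.01, and of somatotropes -0.07, -0.24 and -0.24. After eNampt, Oacyl of the melanotrope list (0.98) and Angpt1 of the lactotrope list (2.22) rose when adjusted over the list alone (adjusted p = 0.0440 and 0.0452), and neither passed over all genes. Oacyl was at 0.53 without eNampt array 2.

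NF-kB targets had means of -0.00 after CRH and 0.04 after IL-6, with camera adjusted p of 0.478 and 0.487. The means were -0.39 and -0.35 (adjusted p = 0.0951 and 0.142) without control arrays 3 and 4, which were low on this list. In 23 of 192 list tests the sign of the mean differed from the direction camera gave, which compares a list with the other genes. None of these was called, the smallest adjusted p among them being 0.36.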
